A study of Mus musculus with 10 samples.

How the data were processed

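Posterior eye tissue of 5 mice was measured by RNA sequencing, with a left-eye and a right-eye library from each animal. Per the labels, libraries were made from 1 μg of total RNA with a stranded total RNA kit after ribosomal RNA depletion. Per the labels the tissue was RPE, choroid and sclera, although their extraction protocol speaks of retinae, so what was handled at extraction is not certain. Which eye wore the lens is not given in the sources used here.

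The authors deposited normalized values that fit CPM with an offset of 1e-04, which was subtracted. The submitters' processing notes name STAR, Partek and the genome build GRCm38 (mm10), and the versions, the annotation release and the use of strand in counting are not given in the sources used here. Among 25737 genes matched by name and chromosome, 99.4% of starts and 99.3% of ends equalled those of GENCODE M21. Here and where coordinates are printed (1-based), starts are as deposited and ends are the deposited stop minus 1. In each library 88.6% to 89.8% of low values (0.5 to 20 steps) were whole multiples of a step within a tolerance of 0.05. The step thus gave an implied depth, but the remaining low values were not whole, so whole reads could not be recovered for every gene. The listed genes summed to under 50% of the CPM total, and what the remaining reads were is not known. The floor of 3 reads covers counting error only. The 95% intervals come from limma and rest on how the right minus left difference varied between animals. Because CPM is relative, a transcript class that takes a larger share lowers all others, and 3 abundant noncoding RNAs took 4.06% to 5.63% of each library.

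Values were tested as log2(CPM + 0.230), a pseudocount of 0.5 in CPM of the listed genes alone, whose sum had a median of 460382 CPM. A log2 difference on this scale understates the change of low genes. Genes with a mean of at least 1 CPM over the 10 libraries entered (15414 genes). The test was limma 3.58.1 in R 4.3.3 (linear model, moderated with an intensity trend) with animal and eye side as terms, all 10 libraries and 4 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The estimated correlation was also used with 23 other settings. It was not used with voom, robust moderation, the animal as a random effect, the other pseudocounts or the rod covariate. The 32 lists hold 844 different genes, some of them in more than 1 list. They were written by hand from general knowledge of the tissue, of other cells that dissection could include and of pathways studied in eye growth. List means per library were compared by exact permutation over all divisions into 5 and 5 and over sign flips within animals, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

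The grouping, the main test, the lists, most alternatives and the rule for named genes were set before the data were examined. Named genes were to be up to 12 per direction among those past the threshold, with predicted loci not named. As none passed, the places were filled by the smallest unadjusted p in each direction. For each list the 2 members with the highest mean level and members past the threshold could also be named. The result of 1 gene chosen by this rule is not reported here.

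The animal entered as a block because the protocol compares fellow eyes and the titles share animal numbers. Sex-linked genes were checked, and 0 animals had eyes that differed. The correlation of fellow eyes was over 0.1 in 2 of 5 animals. Each pair of libraries was checked for duplicate deposits on implied reads of 18922 genes, and all 45 pairs differed beyond sampling noise (chi-square per degree of freedom 12.8 to 69.7).

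The scripts were tested on simulated data. In negative binomial counts for 15395 genes, 56.7% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97% of those changed 4-fold were recovered, with 9 false calls. With known folds placed into the deposited values of 15414 genes, 58.2%, 82.1% and 97% were recovered, with 0 false calls. In both, 67, 67 and 66 genes with a mean of at least 2 CPM were changed at once, so the rates hold for that setting. Alternatives covered the animal block, scaling, pseudocount, filter, library weights, robust moderation, tissue covariates, each animal or library left out, and list tests. Limma's voom on implied reads, a fit with 4 tissue covariates and a collagen list without 2 genes were added after the data were seen. So were the 23 other settings that used an estimated correlation.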

Results

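Total RNA from the posterior wall of the mouse eye was profiled by RNA sequencing in 10 libraries from 5 wild-type C57BL/6J animals, with 1 library from the left eye and 1 from the right eye of each animal. The tissue was labelled as retinal pigment epithelium (RPE), choroid and sclera, that is, the pigmented layer under the retina, the vascular layer behind it and the collagen-rich outer coat. A -20 D lens, which moves the focal plane behind the retina and induces myopia in young animals, was worn over 1 eye from postnatal day 24 for 10 days, and tissue was taken at postnatal day 34. The labels gave the side of each eye but not which eye wore the lens. The libraries were therefore grouped as left eye (n = 5) and right eye (n = 5), and the sign of a difference between these groups has no treatment meaning. If the side of the lens varied between animals, the comparison contains at most part of the lens effect.

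The deposited file listed 26360 genes as counts scaled to the library total (CPM). Steps between low values implied library totals of 66.9 to 94.3 M reads (M, mega; median 79.3 M). The listed genes summed to 42.7% to 47.1% of the CPM total per library, or 30.6 to 43.6 M implied reads, so that a gene needed 0.0318 to 0.0448 CPM to reach 3 reads. Between 24337 and 25076 genes were above 0 in each library.

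Genes of the sclera and RPE were among the named genes with the highest levels in both eyes. The fibrillar collagen genes Col1a2 (2683 ± 464 CPM in left and 2748 ± 425 CPM in right eyes, SD, n = 5 each) and Col1a1 (2104 ± 417 and 2118 ± 454 CPM), which encode the chains of type I collagen, were accompanied by Timp3, an inhibitor of matrix metalloproteinases (2031 ± 251.5 and 2202 ± 315 CPM). Rgr, which encodes an opsin of the RPE, stood at 1816 ± 82.9 CPM in left and 2113 ± 355 CPM in right eyes. The pigment synthesis genes Dct (1550 ± 136 and 1505 ± 203 CPM) and Tyrp1 (1114 ± 130 and 1138 ± 169 CPM) and the small proteoglycan gene Dcn (1787 ± 205 and 1877 ± 195 CPM) were at similar levels. Transcripts of other cells were present as well, led by Ttn, the giant sarcomere protein of muscle, at 3741 ± 2005 CPM in left and 3323 ± 1048 CPM in right eyes.

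The first comparison asked which genes differed between the right and left eyes of the same animals, the nearest the labels allow to the comparison of a lens-treated with an untreated eye. None of the 15414 genes tested passed an adjusted p of 0.05 in limma with the animal as a block (smallest adjusted p = 0.9998), and none of the 13196 protein-coding genes among them did. The genes with the smallest p had small differences, and 3 of the 24 named by rule are given here, of which Cox7c had the smallest p. Cox7c, a subunit of cytochrome c oxidase (chromosome 13, 86044816 to 86046904, minus strand, GRCm38), was at 10.8 ± 2.27 CPM in left and 8.53 ± 1.47 CPM in right eyes, a log2 difference of -0.32 ± 0.06 (SE). Sv2b, a synaptic vesicle glycoprotein (chromosome 7, 75114894 to 75309262, minus strand), was at 162 ± 9.33 and 180 ± 7.04 CPM, a log2 difference of 0.15 ± 0.05 (SE). Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages (chromosome 7, 110850607 to 110863239, minus strand), was at 2.70 ± 0.976 and 1.72 ± 0.470 CPM, a log2 difference of -0.56 ± 0.15 (SE).

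At an unadjusted p under 0.05, limma counted 430 genes, 124 higher and 306 lower in the right eye, against 771 expected by chance. The 12 genes with the smallest p in each direction all missed the adjusted threshold (adjusted p = 0.9998 for each in limma), and each had the same direction in 5 of 5 animals, which a small p in a fit blocked on the animal favours. Over all genes tested 4.44% had the same direction in 5 of 5 animals, against 6.25% expected by chance. On the higher side these were Rd3l, Cfap54, Fam122a, Clec3a, Nell2, Pigz, Sv2b, Fam89b, Chrm3, Tmem108, Ovca2 and Tdrd9, with log2 differences of 0.15 to 0.47. Chrm3, which encodes the muscarinic acetylcholine receptor M3 (chromosome 13, 9875486 to 10360847, minus strand), was at 3.69 ± 0.574 CPM in left and 4.52 ± 0.591 CPM in right eyes, a log2 difference of 0.28 ± 0.09 (SE). On the lower side they were Cox7c, Galnt2, Sar1b, Cd302, Rpl36al, Bves, Efna5, Plin4, Mybl1, Lyve1, mt-Nd3 and Cobll1, with log2 differences of -0.23 to -0.56. The mitochondrial gene mt-Nd3, a subunit of complex I, was at 72.9 ± 8.52 and 58.6 ± 12.6 CPM, and Plin4, a coat protein of lipid droplets, at 54.7 ± 8.10 and 45.7 ± 10.4 CPM. Of the 24 genes, 15 overlapped another listed gene, 9 of them on the same strand, and their values are uncertain to that extent. Rd3l lies inside Tdrd9 on the opposite strand, and Fam122a and Ovca2 overlap Pip5k1b and Dph1.

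**Figure D1:**
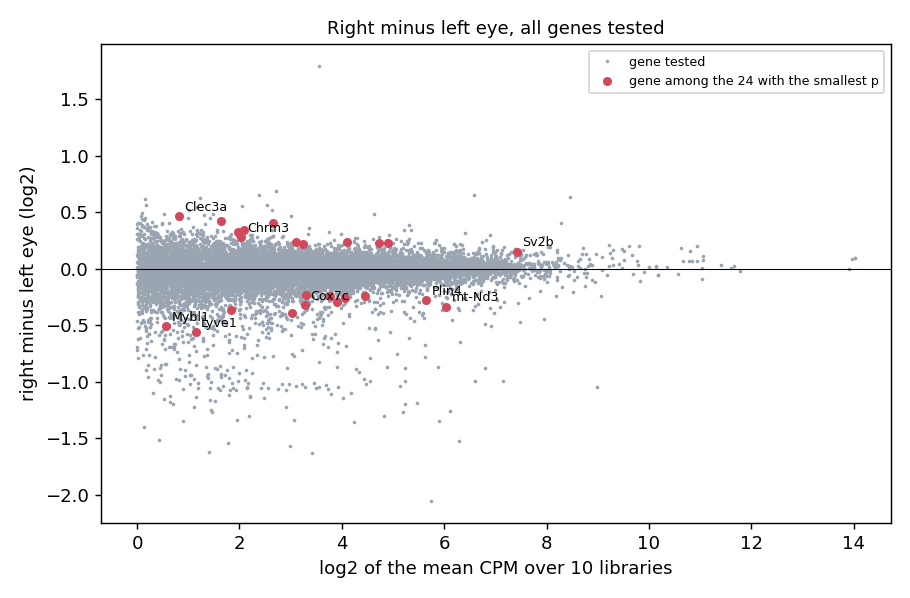
Mean level of each of the 15414 genes tested (log2 of the mean CPM over 10 libraries, horizontal axis) against its right minus left difference (log2, vertical axis). Red points are the 24 genes with the smallest p, 12 in each direction, with log2 differences of 0.15 to 0.47 and -0.23 to -0.56, and none passed an adjusted p of 0.05 in limma.

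The precision of this comparison differed between genes. The median standard error was 0.09 on the log2 scale, and the 95% interval reached a median of 0.21 (1.16-fold) to either side of the estimate. For 14769 genes (95.8%) the 95% interval lay within a 2-fold difference in either direction. Myh4, a fast myosin of skeletal muscle, was outside this set, with a 95% interval from -2.20 to 0.11. On deposited values into which known folds had been placed, the same test called 58.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97% of those changed 4-fold. The folds were placed at once into 67, 67 and 66 genes with a mean of at least 2 CPM. As adjusted p depend on how many genes change, the rates may be lower where few genes differ, or for lower levels.

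The second comparison asked whether groups of genes differed between the eyes. By limma's camera test with a preset correlation of 0.01 between genes, 7 of the 32 lists differed from the other genes, 4 lower and 3 higher in the right eye. With an estimated correlation none of the 32 did (adjusted p = 0.989 for each of the 7 with an estimated correlation), and none passed limma's fry test (smallest adjusted p = 0.995). The estimated correlation of the 7 lists was 0.402 (ribosomal proteins) to 0.873 (surface epithelium), far above the preset. Their camera p at the preset therefore overstate the evidence. No member of any list passed over all genes tested. Adjusted over the list alone, 2 members passed, Plin4 among the adipocyte markers (adjusted p = 0.0307 in limma) and Cox7c in oxidative phosphorylation (adjusted p = 0.0496 in limma). This takes no account of the 32 lists looked at, so a few such passes can arise by chance. The adipocyte list had only 6 measured genes.

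Markers of surface epithelium, the corneal and conjunctival covering of the front of the eye, gave the lowest of these 7 adjusted p (camera adjusted p = 5.39e-10, and 0.989 with an estimated correlation). All 17 measured members were lower on average in the right eye, with a list mean difference of -1.02 on the log2 scale (SD of the animal differences 1.51, lower in 4 of 5 animals, exact permutation p = 0.111 over all divisions into 5 and 5, two-sided). The keratin gene Krt15 was at 120 ± 35.4 CPM in left and 74.2 ± 60.4 CPM in right eyes, and Aldh3a1, a corneal aldehyde dehydrogenase, at 144 ± 73.3 and 77.9 ± 44.8 CPM. Without both eyes of animal 61, the only animal with the higher level in the right eye, the list mean difference was -1.59 with an exact permutation p of 0.0286, and without the right eye of animal 61 it was -1.40 with an exact permutation p of 0.0238. It was -0.61 (exact permutation p = 0.371) without animal 66, -0.75 (0.286) without animal 65, -0.75 (0.206) without the right eye of animal 65 and -0.45 with array weights. These divisions ignore that the libraries are fellow eyes. Sign flips within the 5 animals gave an exact p of 0.25 for this list, and with 4 animals they cannot reach 0.05.

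The RPE list was higher in the right eye by camera (adjusted p = 1.79e-08, and adjusted p = 0.989 with an estimated correlation), with 15 of 16 members higher, a mean difference of 0.11 and the higher level in 3 of 5 animals. Rgr differed by 0.20 ± 0.10 (log2, SE), and Ttr, which encodes the retinol carrier transthyretin, by 0.19 ± 0.12 (log2, SE). In each of the 5 animals the eye with the higher RPE list mean had the lower rod list mean, and the same held for lens crystallins and for smooth muscle and pericytes. The exact permutation p of the RPE list mean was 0.159, and 0.0476 without the right eye of animal 68. With animals or libraries left out in turn, the mean difference lay between 0.06 (without animal 65) and 0.16 (without the right eye of animal 68). Markers of choroidal endothelium were higher in the right eye by camera (adjusted p = 0.000407, and adjusted p = 0.989 with an estimated correlation), with 16 of 18 members higher and a mean difference of 0.08, higher in 4 of 5 animals. Kdr, the main receptor for vascular endothelial growth factor, was at 102 ± 6.00 CPM in left and 110 ± 13.9 CPM in right eyes. Without both eyes of animal 66 the camera adjusted p of this list was 0.0518, and without the right eye of animal 66 it was 0.124. Its mean difference lay between 0.03 (without animal 65) and 0.15 (without animal 68).

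Genes for cytosolic ribosomal proteins were lower in the right eye by camera (adjusted p = 3.11e-06, and adjusted p = 0.989 with an estimated correlation), with 49 of 53 members lower, a mean difference of -0.09 and the lower level in 4 of 5 animals. Immediate early genes, which respond within minutes to stimuli and handling, had 19 of 21 members lower (camera adjusted p = 0.000276, and adjusted p = 0.989 with an estimated correlation), with a mean difference of -0.16, lower in 4 of 5 animals. In oxidative phosphorylation 41 of 52 members were lower (camera adjusted p = 0.000571, and adjusted p = 0.989 with an estimated correlation), with a mean difference of -0.06, lower in 4 of 5 animals. Among lens crystallins 17 of 21 members were higher in the right eye. The list of 21 gave a camera adjusted p of 0.0271 (adjusted p = 0.989 with an estimated correlation) and a mean difference of 0.18, higher in 3 of 5 animals. The camera adjusted p of ribosomal proteins was 0.0518 without animal 66 and 0.651 with 4 tissue covariates and no block (mean -0.04 each). Their mean reached -0.15 without the left eye of animal 65, an outlier for this list. That of immediate early genes was 0.0530 without animal 64, 0.0628 without animal 68, 0.0796 without the left eye of animal 66, 0.123 without the right eye of animal 64 and 0.504 without the right eye of animal 68, with means between -0.06 (without that eye) and -0.24 (without animal 65). That of oxidative phosphorylation was 0.0569 without animal 64, 0.357 without animal 68, 0.343 and 0.832 without the left eye of animal 64 or 68, and 0.216 and 0.0735 without the right eye of animal 61 or 66. It was 0.197 with 4 tissue covariates and no block (mean -0.04), and the means lay between -0.01 (without the left eye of animal 68) and -0.12 (without animal 65). The lens crystallin call was lost without animal 61 (0.444) or 66 (0.117), without the left eye of animal 66 (0.299) or 68 (0.0649) and without the right eye of animal 64 (0.510) or 66 (0.0640). The lens crystallin mean turned to -0.08 without animal 65 and to -0.06 without the left eye of animal 61. It was -0.09 without the right eye of animal 65, which held 363 CPM of Cryaa, and the camera adjusted p of that list was 0.0997 without the animal block and 0.109 with the animal as a random effect. It was 0.0688 after median-of-ratios scaling, 0.0847 after quantile normalization, 0.0580 with a filter of 5 CPM and 0.0658 with robust moderation.

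**Figure D2:**
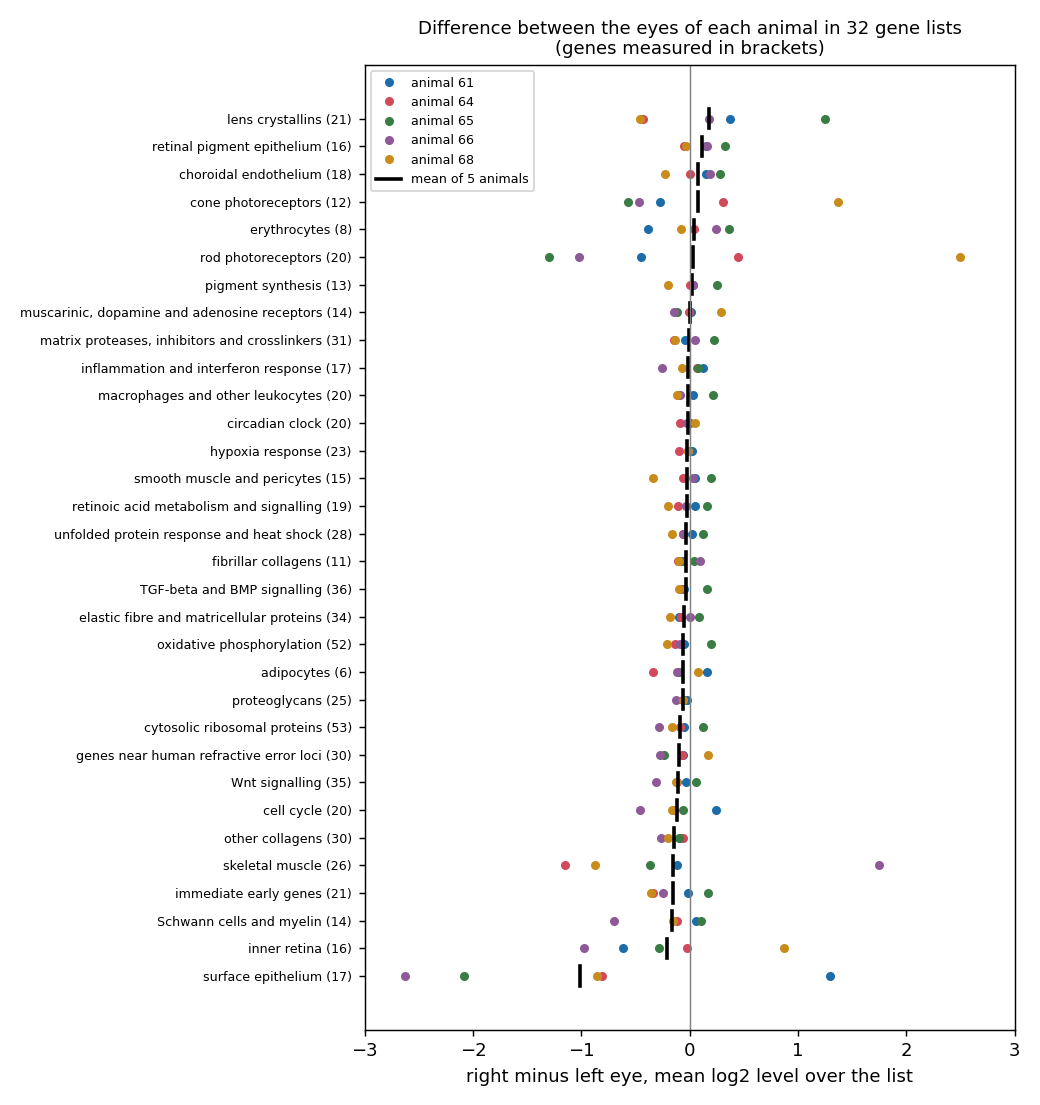
Right minus left difference of the mean log2 level of 32 gene lists (horizontal axis) in each of 5 animals (coloured points), with the mean of the 5 as a black bar. The animals scattered on both sides of 0 for 30 lists, while the lists of other collagens (-0.14) and proteoglycans (-0.07) were lower in the right eye in 5 of 5 animals.

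With the animal block, the values as deposited and all libraries at equal weight, the matrix lists of the sclera did not pass the camera test in either direction. Other collagens, 30 measured genes outside the fibrillar group, had a list mean lower by -0.14 on the log2 scale in the right eye (SD 0.0858, lower in 5 of 5 animals), with a median member difference of -0.01 and 17 of 30 members lower. This gave an exact permutation p of 0.00794 over all divisions into 5 and 5, the smallest they can give, and an adjusted exact p of 0.254 over the 32 lists. Their most abundant members went the other way, with Col12a1 at 1685 ± 223 CPM in left and 1868 ± 149 CPM in right eyes, and Col8a2 at 524 ± 39.0 and 566 ± 57.5 CPM. The proteoglycan list mean was lower by -0.07 in 5 of 5 animals (exact permutation p = 0.0397, adjusted 0.635), while Dcn and Fmod (389 ± 40.0 and 412 ± 34.0 CPM) were each higher on average in the right eye. The exact permutation p of the proteoglycans was 0.114 without animal 64 and 0.0571 without animal 65, 66 or 68. It was 0.0794 without the left eye of animal 61, 64 or 66 or the right eye of animal 68, 0.0635 without the right eye of animal 64 or 66 and 0.0714 without the right eye of animal 65. Sign flips within the 5 animals cannot give an exact p under 0.05, and both lists stood at the smallest value that test can give. Fibrillar collagens (mean difference -0.03, camera adjusted p = 0.643), matrix proteases, inhibitors and crosslinkers (-0.01, 0.983) and elastic fibre and matricellular genes (-0.06, 0.148) did not pass. The fibrillar collagen mean ran from -0.08 (without the right eye of animal 66) to 0.03 (without the left eye of animal 68). That of matrix proteases, inhibitors and crosslinkers ran from -0.07 (without animal 65) to 0.02 (without animal 64), and neither list was called in any setting. The elastic fibre and matricellular list was called lower in the right eye in 8 of 31 alternatives, with camera adjusted p of 0.0282 after quantile normalization, 0.0157 with array weights and 0.0135 with 4 tissue covariates and no block. The others were 0.0149 without animal 65, 0.00317 without animal 66, 0.0466 and 0.0219 without the left eye of animal 64 or 65, and 0.00519 without the right eye of animal 66. The mean lay between -0.09 (without animal 65) and -0.02 (without animal 68). With an estimated correlation it was called in none of 23 settings, these 8 included (smallest adjusted p = 0.686).

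Among cell type lists, pigment synthesis (mean difference 0.02, camera adjusted p = 0.352), smooth muscle and pericytes (-0.02, 0.950), Schwann cells and myelin (-0.16, 0.640), erythrocytes (0.04, 0.236), macrophages and other leukocytes (-0.01, 0.779) and adipocytes (-0.06, 0.607) did not pass. Nor did rods (0.03, 0.331), cones (0.07, 0.190), inner retina (-0.21, 0.603) and skeletal muscle (-0.15, 0.614). Several of these lists were called by camera at the preset correlation when animals or libraries were left out or settings changed, as follows, and none was called in any setting that used an estimated correlation. Skeletal muscle was at -0.63 without animal 66 (adjusted p = 2.87e-17), -0.44 without its left eye (3.34e-07) and -0.34 without its right eye (0.0137), against 0.10 without animal 64 (0.432). Inner retina was at -0.47 without animal 68 (0.000733), -0.42 without its right eye (0.0160) and -0.28 with the skeletal muscle covariate (0.0314). It was at -0.01 without animal 66 (0.689), -0.05 without its right eye (0.635) and -0.08 without the right eye of animal 61 (0.926). Cones were called higher without animal 61 (0.16, 0.0406), 65 (0.24, 0.00349) or 66 (0.21, 0.00818), without the left eye of animal 65 (0.20, 0.0108), without the right eye of animal 61 (0.22, 0.00797) or 66 (0.21, 0.00818) and with voom (0.25, 0.0180), and were at -0.19 without animal 68 (0.484). Rods were called higher without animal 65 (0.37, 1.75e-05) or 66 (0.30, 0.00818), without the left eye of animal 65 (0.29, 0.000373), without the right eye of animal 61 (0.32, 0.000774) or 66 (0.28, 0.00519) and with voom (0.27, 0.0103). They were called lower without animal 68 (-0.58, 1.14e-08) or its right eye (-0.46, 8e-04). Pigment synthesis was called higher without animal 68 (0.08, 0.00419) or its right eye (0.08, 0.00732), and erythrocytes without animal 61 (0.14, 5.69e-05) or the left eye of animal 66 (0.14, 0.0359). Pigment synthesis was at -0.03 without animal 65 (0.931) and erythrocytes at -0.08 without the right eye of animal 66 (0.464). With an estimated correlation the smallest adjusted p over 22 or 23 settings, voom not among them, was 0.792 for skeletal muscle and inner retina, 0.747 for rods and cones, 0.575 for pigment synthesis and 0.749 for erythrocytes. The remaining lists were called in no setting, but their means moved with animals or libraries left out. They ran from -0.23 to -0.03 for Schwann cells and myelin and from -0.12 to 0.005 for adipocytes. For smooth muscle and pericytes they ran from -0.08 to 0.05, and for macrophages and other leukocytes from -0.07 to 0.06.

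Among pathway lists, retinoic acid metabolism and signalling (-0.03, 0.637), TGF-beta and BMP signalling (-0.03, 0.779), Wnt signalling (-0.11, 0.140), hypoxia response (-0.02, 0.723) and inflammation and interferon response (-0.01, 0.950) did not pass. The unfolded protein response and heat shock (-0.03, 0.801), cell cycle (-0.11, 0.0542), circadian clock (-0.02, 0.607), the list of muscarinic, dopamine and adenosine receptors (0.01, 0.603) and genes near human refractive error loci (-0.10, 0.522) did not pass either. The receptor list also held other genes, among them Igf1r and Igf2, its members with the highest levels. The cell cycle list was called lower in 9 of 31 alternatives, with camera adjusted p of 0.0400 after median-of-ratios scaling, 0.00417 without a filter and 0.0314 with the skeletal muscle covariate. The others were 0.000152 without animal 61 (mean -0.20), 0.00885, 0.00366 and 0.0359 without the left eye of animal 61, 64 or 66, and 0.00726 and 0.00216 without the right eye of animal 61 or 68, while the mean was -0.03 without animal 66 (0.660). With an estimated correlation it was called in none of 23 settings, these 9 included (smallest adjusted p = 0.747). Wnt signalling was called lower without a filter (0.0217), with array weights (0.0487), without animal 65 (0.0280) and without the left eye of animal 68 (0.0178), and in none of 23 settings with an estimated correlation (smallest adjusted p = 0.747). With animals or libraries left out, the mean of genes near human refractive error loci ran from -0.16 (without animal 68) to -0.05 (without animal 66), with no call. That of retinoic acid metabolism and signalling ran from -0.08 to 0.03. The means of TGF-beta and BMP signalling, inflammation, the unfolded protein response, the circadian clock and the receptor list also changed sign. The mean, the median and the camera direction differed in sign for 6 lists, none of them among the 7, namely fibrillar collagens, proteoglycans, macrophages and other leukocytes, TGF-beta and BMP signalling, hypoxia response and inflammation and interferon response.

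The third comparison concerned how much of other tissues each library held. Rod transcripts varied most, with a list mean that spanned 3.14 on the log2 scale (8.83-fold) between the right eye of animal 61 and the right eye of animal 68. Gnb1, a G protein subunit used by rods and other cells, ranged from 110.9 to 229.8 CPM. Surface epithelium spanned 2.77, lens crystallins 2.35 and skeletal muscle 1.92 on the log2 scale, while hypoxia response spanned 0.14. The rod list was higher in the right eye in animals 64 and 68 and lower in animals 61, 65 and 66, and the mean difference over the 5 animals was 0.03 (SD 1.53, exact permutation p = 0.968). Without animal 68 it was -0.58, and without the right eye of animal 68 it was -0.46. Skeletal muscle differed by 1.75 between the eyes of animal 66 and by -1.15 between those of animal 64, and Myh4 was at 699 ± 456 CPM in left and 309 ± 137 CPM in right eyes, a log2 difference of -1.04 ± 0.49 (SE, adjusted p = 0.9998 in limma).

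**Figure D3:**
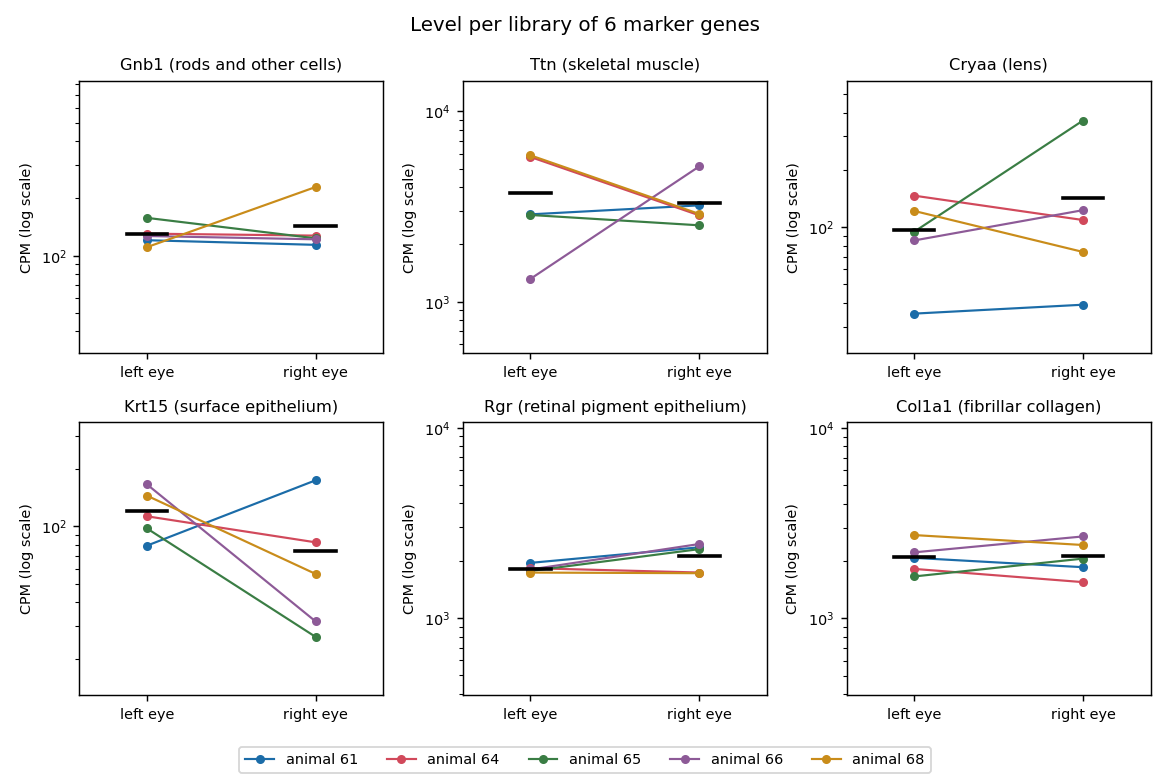
Level (CPM, log axis) of 6 marker genes in the left and right eye of 5 animals, each line joining the eyes of 1 animal and black bars giving group means. Gnb1 was at 229.8 CPM in the right eye of animal 68, and the lines of Ttn and Krt15 crossed in both directions.

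The last comparison asked whether the eyes of 1 animal resembled each other. Sex-linked genes gave the same answer in both eyes of every animal, with Xist, the RNA that silences the inactive X chromosome, at 729 to 868 CPM in both eyes of 2 animals and the Y-linked gene Ddx3y at 47.6 to 55.4 CPM in both eyes of the other 3 animals. Over all genes the correlation of deviations from the group means between fellow eyes lay between -0.19 and 0.27, computed across genes, which are not independent replicates. A distance between 2 eyes was taken as the SD of their log2 difference over genes, without X, Y and mitochondrial genes. Its mean was 0.373 between fellow eyes, against 0.370 between eyes of different animals (exact permutation p = 0.533 over 120 pairings, one-sided for closer fellow eyes).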

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

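The tests of rod carry-over, depth and both explanations of the collagen pattern were chosen after those results were seen, as was the allowance for spread used to read the rod covariate test.

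Values far from the other 4 libraries of the same side were searched for in 240 groups of 5 values, and 15 were found where about 12 arise by chance. In the left eye of animal 65, Ctnnb1 was at 344 CPM (377 to 388 CPM in the other left eyes), Rplp0 at 109 CPM (130 to 137 CPM) and the listed genes at 42.7% of the CPM total (45.7% to 46.3%). The same library had list means of 4.37 for ribosomal proteins (4.62 to 4.66 in the others) and 4.35 for matrix proteases, inhibitors and crosslinkers (4.56 to 4.63) on the log2 scale. In the left eye of animal 66 the Schwann cell list mean was 3.95 (3.44 to 3.53), and in the left eye of animal 64 the adipocyte list mean was 3.31 (2.92 to 3.01). In the right eye of animal 68, Gnb1 was at 230 CPM (114 to 128 CPM in the other right eyes). In the right eye of animal 65, Cryaa was at 363 CPM (39.1 to 123 CPM) and Cryba1 at 159 CPM (21.66 to 60.99 CPM). In the right eye of animal 66, Ttn was at 5147 CPM (2522 to 3211 CPM), Hbb-bs at 519 CPM (281 to 337 CPM), Hba-a1, whose reads can be shared with its near-identical copy Hba-a2, at 328 CPM (166 to 212 CPM), and the mean of other collagens at 5.05 (5.15 in the lowest and highest of the others). Bves was at 4.49 CPM in the right eye of animal 64 (2.50 to 2.94 CPM).

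Rod transcripts differed between libraries in both directions across the eyes. Depth was argued against, because the rod list differed by 2.50 on the log2 scale between the eyes of animal 68, whose implied totals were 94.2 and 94.3 M reads. Retinal tissue carried over at dissection may account for the pattern, since the cone list moved with the rod list in 5 of 5 animals, and 19 abundant rod genes differed in animal 68 by a mean of 2.51 (SD 0.717). The inner retina list moved with the rod list in 4 of 5 animals. It differed by only 0.87 in animal 68, and went against the rods in animal 64 (-0.03 against 0.44). Whether the rod level follows lens wear stays open, because the treated side is not given. No gene passed limma in any of the 16 splits that part all 5 pairs (smallest adjusted p 0.114), with 361 to 2169 genes at an unadjusted p under 0.05. If 1 eye of each animal wore the lens, these splits include the one by lens wear, but which of the 16 that is remains unknown.

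The other collagens were lower in the right eye in 5 of 5 animals. Chance among 32 lists stays open, with an adjusted exact p of 0.254. A list at the smallest p of the divisions falls under 0.05 after this adjustment only if several other lists also have a small p. The adjusted test therefore cannot decide on chance for a single list. Collagens of surface epithelium, Col7a1 and Col17a1, may contribute, since without them the mean was lower in 4 of 5 animals (-0.08, exact p = 0.0635), but leaving out genes that were themselves lower weakens a list by construction. Whether it follows lens wear stays open, because the treated side is not given.

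Fewer genes had a small p than chance would give, 430 against 771. Variation shared by many genes may account for this, since the other splits that part all 5 pairs gave up to 2169 genes. The split with 2169 was picked for its count. Rods, cones, RPE, lens crystallins, and smooth muscle and pericytes were each ordered as in this split in 5 of 5 animals. About 2 such lists arise by chance, and these 5 moved together, so they are not separate cases. The split thus parted the eyes of each animal by rod level, among others. With the rod list as a covariate the count was 710, below 771 by less than 452. That value is the SD of the counts of the 16 splits, fitted without the rod covariate. This test therefore cannot decide on unequal rod content. The test as first written would have counted 710 against that explanation.

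Other splits of the 10 libraries into 5 and 5 were counted. For genes, the real split gave 0 in limma and 434 at an unadjusted p under 0.05, and the highest other gave 2. With a real count of 0, 100 of 100 splits gave as many by construction, so this says nothing on chance. For lists, the real split gave 6 without the block, 87 of 100 splits gave as many and the highest other gave 18, so chance cannot be excluded for the list calls.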

How the results depend on the processing

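Voom on implied reads, the fit with 4 tissue covariates and the collagen list without 2 genes were chosen after the data were seen. The same holds for the 23 other settings that used an estimated correlation. No gene passed in limma under any of 30 alternatives, with 254 to 903 genes at an unadjusted p under 0.05 (smallest adjusted p 0.268, with the skeletal muscle covariate, which also gave the 903). Leaving out single animals or libraries gave 0 genes each time. Without the animal block, 0 genes and 6 lists passed, and leaving out the pairing changed no call other than that of the lens crystallins, which was lost in 17 of 30 alternatives. Voom gave 0 genes, 510 at an unadjusted p under 0.05, and 9 lists.

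The count of 7 lists became 0 with an estimated correlation (also 0 in each of 23 other settings that used one), 0 with fry and 4 without the block but with 4 tissue covariates, and was 5 to 10 with animals or libraries left out. The first 2 alternatives allow for the correlation of list members, and the covariates include 2 of the 7 lists, surface epithelium and lens crystallins, which could not be called. Why ribosomal proteins and oxidative phosphorylation were lost there was not tested. Of 984 values for single lists, 45 lost a call and 46 gained one. The lens crystallin mean reversed to -0.0838 without animal 65, -0.0640 without the left eye of animal 61 and -0.0947 without the right eye of animal 65, and was at most 0.382. The rod mean reversed to -0.58 without animal 68 (camera adjusted p = 1.14e-08) and -0.46 without its right eye, the library with the highest rod level, and was at most 0.368.

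Proteoglycans (-0.07) missed an exact p of 0.05 with a filter of 5 CPM (-0.0839, exact p = 0.0635), and in 11 of 15 fits with an animal or library left out (means -0.0520 to -0.0680, exact p 0.0571 to 0.114). Over all 15 the means lay between -0.0520 and -0.0823. Other collagens missed it without Col7a1 and Col17a1 (-0.0808, exact p = 0.0635). Surface epithelium passed it without animal 61 (-1.59) or its right eye (-1.40), with a range up to -0.614, and was at -0.452 in limma with array weights. The RPE list passed it without the right eye of animal 68 (0.159, exact p = 0.0476), with a range down to 0.0580, and the cause was not tested. The depth floor of 3 reads, 0.0318 to 0.0448 CPM, lies below the filter of a mean of 1 CPM.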

Other observations

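The tests of differences between animals were added after the data were seen, the circadian list was picked after its rank among 32 lists was known, and the reading of both pairing tests was changed after their values were seen.

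Levels that differed between animals and were shared by fellow eyes were looked for with limma, testing the animal term with eye side in the model. At an adjusted p of 0.05, 13 genes passed, of which 7 lie on the X or Y chromosome (Ddx3y, Kdm5d, Eif2s3y, Uty, Xist, Kdm6a and Eif2s3x). The other 6 were Fmo2, Gm49838, Zbtb16, Tgtp1, Gm1966 and Fkbp5, named after their values were seen. Fkbp5 and Zbtb16, which are known to respond to glucocorticoids, ranged from 15.9 to 40.1 CPM and from 17.2 to 51.7 CPM between animal means, both highest in animal 68. Fmo2, a flavin monooxygenase, ranged from 35.8 to 92.9 CPM, and Tgtp1, an interferon-induced GTPase, from 2.42 to 10.5 CPM. A state shared by both eyes of an animal may account for such genes. Sex is part of the animal term and was not a separate term in the model. Of the 6 genes, Tgtp1 alone was higher in both animals with high Xist than in the other animals. It was at 10.5 and 8.06 CPM in animals 61 and 65, and at 2.42 to 5.56 CPM in animals 64, 66 and 68. In a fit on autosomal genes alone the true pairing of left with right eyes gave 4 genes, and 6 of 100 pairings, the true one included, gave at least as many (highest other 7), so this cannot be told apart from chance with so few genes. The test as first written would have counted this against a shared state.

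Circadian clock genes had the highest median F for the animal term among the 32 lists, 9.05 against 1.14 for all genes. The transcriptional repressor gene Nr1d1 ranged from 6.20 to 22.1 CPM between animal means and Dbp from 20.9 to 43.0 CPM, both named after their values were seen. A state shared by both eyes, such as the hour of tissue collection, may account for this, since 1 of 100 pairings, the true one alone, gave as large a median F (highest other 6.37). The list was 1 of 32, and the adjusted share was 0.192. As 1 of 100 is the smallest share these pairings can give, 1 list alone cannot fall under 0.05 after that adjustment. It therefore cannot decide on chance among 32 lists, which remains open, and the shared state is a hypothesis. The test as first written, without that adjustment, would have counted in favour of a shared state. The hour of collection is not given in the labels.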
